A study of Drosophila melanogaster with 27 samples.

How the data were processed

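The submitted table of counts per gene held 27 libraries of which 0 pairs were identical. According to the submitters, reads were produced with bcl2fastq 2.20, trimmed with Trim Galore and aligned with STAR, and their notes give neither the genome build, the strand used in counting nor whether molecular barcodes were used to remove duplicates. The table ends in 5 special entries for reads without a gene, which were left out. They held 23.8% to 74.7% of the reads of a library. Gene symbols, lengths and positions came from the Ensembl annotation of the fly assembly BDGP6.54, in which 17710 of 17807 identifiers were found.

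Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15), which removed 6338 and left 11469. Libraries were scaled with TMM, and 1 robust quasi-likelihood model with 6 groups was fitted to all 27 libraries (biological coefficient of variation 0.281). From it came 8 comparisons: Fmr1 against IgG and Fmr1 against input in each genotype, the differences of these between genotypes, and mutant against wild type in inputs and in IgG libraries. P-values of each comparison were adjusted with the Benjamini-Hochberg method, and those under 0.05 passed. Log2 fold changes are those of the model and are given with their SE, so they are not damped by the prior count of 2 used for log2 CPM. Levels are TMM-scaled CPM, given with the SD. An exact permutation test over all splits was run for Ythdf in the inputs.

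The 29 gene lists, written from general knowledge before the data were examined, hold 531 entries of which 525 were found: published Fmr1 target mRNAs, m6A pathway, axon guidance and growth, actin and microtubule cytoskeleton, synaptic vesicle and active zone, voltage-gated and potassium channels, neurotransmitter receptors, very large proteins, chromatin regulators, RNA granule and RNA-binding proteins, translation factors, ubiquitin ligases and proteasome, heat shock and stress, immune response, neuron, glia, photoreceptor, muscle, fat body and hemocyte markers, dosage compensation and sex, eye pigment, ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrial genome, mitochondrial ribosomal proteins, cuticle proteins, small structured noncoding RNA and ribosomal RNA. Each was tested with camera of limma 3.58.1 at its preset correlation, and again with an estimated correlation and with fry, adjusted over the lists. Camera compares the limma voom statistics of a list with those of the other genes. It does not test the median printed beside its p-value. Counts adjusted over the list alone use the p-values of its members only.

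Genes were named by a rule: in each comparison the 10 with the largest change in each direction among those past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups (where fewer passed, the 5 with the smallest p), up to 4 members of each list with the smallest p, and in every comparison Ythdf, Fmr1, futsch, chic, Rac1 and the m6A list. The rule gives 1063 values, too many to print, and the text holds 258 of them. Beyond the genes named in every comparison, these were picked after their values were seen, with preference for genes whose call holds when any 1 library is left out, so they look steadier than the rest. Of 159 called values in the text 9 (5.66%) lose the call without some library, against 84 of 418 (20.1%) among those the rule gives and the text leaves out. All were computed. Some genes with few counts in a group are given as levels and others as fold changes, which then rest on few counts. Noncoding genes that overlap others were passed over, also after their values were seen. Correlations of the deviations from group means of same-numbered libraries were 0.63 to 0.776 for Fmr1 and 0.137 to 0.244 for IgG libraries of both genotypes and −0.0473 to 0.394 for inputs. Within a genotype they were −0.0843 to 0.508 between Fmr1 and IgG and 0.228 to 0.442 between Fmr1 and input in the wild type, and 0.359 to 0.516 and 0.265 to 0.49 in the mutant. The protocol divides a lysate into input and both pull-downs, and the labels do not say whether a number is shared between genotypes. DESeq2 1.42.0 and limma voom were run as alternatives. In the self-test, counts were simulated for 5 of the 8 comparisons from the levels, dispersions and depths of these libraries, with planted changes in 100 genes per fold. The planted genes were drawn from those with a mean CPM of at least 2. Libraries were drawn independently, without the correlations between same-numbered libraries or within sets of replicates. Recovery of lower genes, and false calls under such correlations, were therefore not tested.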

Results

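Fmr1, the fly counterpart of the protein lost in fragile X syndrome, is an RNA-binding protein that regulates translation of neuronal mRNAs, and Ythdf is a cytoplasmic reader of the RNA mark m6A. RNA was sequenced from pupal heads of wild-type and Ythdf mutant flies as input lysate, as RNA pulled down with Fmr1 antibodies and as RNA pulled down with mouse IgG, to ask whether Fmr1 binds other mRNAs when Ythdf is lost. The labels name the whole brain as source while the protocol describes heads of pupae, and do not describe the mutation. Each kind of library had 5 biological replicates of the wild type and 4 of the mutant, 27 libraries in all. Counts in genes ran from 5623123 to 13240187 in wild-type inputs and 9207492 to 15459370 in mutant inputs, and from 14843961 to 29699547 and 10726339 to 54195136 in the Fmr1 libraries. The IgG libraries were shallower, at 196933 to 5879253 in the wild type and 274951 to 3052311 in the mutant. Of 17807 genes listed, 11469 had enough counts to be tested with edgeR.

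**Figure D1:**
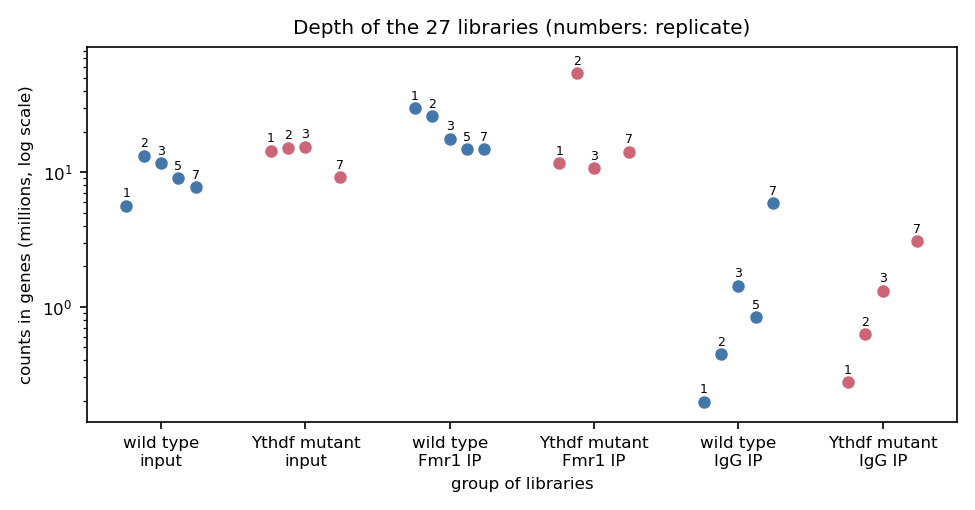
Counts in genes of the 27 libraries, on a log scale, with the replicate number beside each point. The shallowest IgG library held 196933 counts and the deepest Fmr1 library 54195136.

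Ythdf mRNA was lower in every mutant input than in the lowest wild-type input. Its level was 33.2 ± 3.26 CPM (SD, 4 libraries, 29.4 to 36.3) in the mutant against 61.8 ± 5.18 CPM (5 libraries, 55.5 to 69.1) in the wild type, 53.7% of it, so the mutant still held reads from the gene. This is a mean log2 difference of −0.89 with an exact two-sided permutation p of 0.0159 over the 126 splits. In the edgeR fit across all genes the same gene had −0.90 ± 0.32 with adjusted p = 0.107, which did not pass. In the Fmr1 libraries Ythdf stood at 57.5 ± 17.7 CPM in the wild type and 23.4 ± 9.54 CPM in the mutant, and in the IgG libraries at 55.9 ± 25.6 and 32.2 ± 19.7 CPM. Fmr1 mRNA had 71.0 ± 10.9 CPM in wild-type inputs and 70.2 ± 5.45 CPM in mutant inputs (log2 fold change −0.015 ± 0.12, adjusted p = 0.974).

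**Figure D2:**
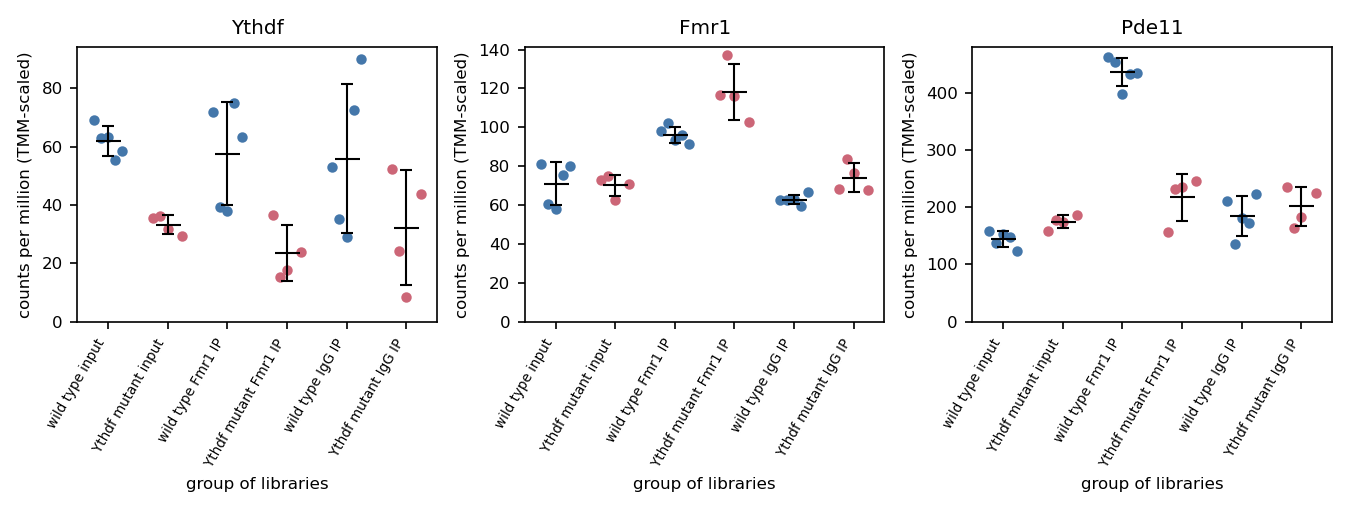
Levels of Ythdf, Fmr1 and Pde11 per library, with means and SDs. Mean Ythdf was 61.8 CPM in wild-type and 33.2 CPM in mutant inputs, and mean Pde11 was 436 CPM in wild-type and 217 CPM in mutant Fmr1 libraries.

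In the wild type, mRNAs of synaptic proteins stood above IgG in the Fmr1 libraries, and small structured RNAs, ribosomal protein mRNAs and fat body transcripts stood below it. As lists these lose their calls with an estimated correlation (adjusted p = 0.123 to 0.356). The highest log2 fold changes (± SE, 5 libraries against 5, no overlap between the groups) were those of RpLP0-like (3.12 ± 0.34), CG9328 (2.37 ± 0.36), CG14435 (2.37 ± 0.39) and CG10669 (2.16 ± 0.23). Others near the top were cactin (2.02 ± 0.25), Trf4-1 (2.00 ± 0.25), Atg4b (1.94 ± 0.21) and sbr (1.94 ± 0.31). RpLP0-like encodes a relative of a ribosomal stalk protein, cactin a splicing factor, Trf4-1 a poly(A) polymerase, sbr the mRNA export receptor and Atg4b an autophagy protease. RNA-binding proteins known from neuronal RNA granules rose too, among them stau (1.65 ± 0.17), Rbp9 (1.40 ± 0.14), tral (1.08 ± 0.16) and Atx2 (1.06 ± 0.16). So did vesicle proteins, with nSyb (1.26 ± 0.17), Snap25 (1.23 ± 0.16) and EndoA (1.17 ± 0.15), and the chromatin regulators brm (1.12 ± 0.16), Kdm5 (0.99 ± 0.15) and ph-p (1.48 ± 0.23). The mRNA of Fmr1 itself, known to be bound by its own protein, rose by 0.61 ± 0.13 (adjusted p = 0.000517). Among mRNAs that fell were Obp99b (−4.44 ± 0.58), Lsp2 (−4.04 ± 0.58) and Lsp1alpha (−3.73 ± 0.50) from the fat body. So did RpL37A (−2.78 ± 0.27) of the ribosome and the giant cytoskeletal linkers shot (−1.30 ± 0.22) and Msp300 (−1.37 ± 0.20). Nuclear or structured noncoding RNAs also fell, with RNaseP:RNA (−2.99 ± 0.28), lncRNA:roX1 (−1.93 ± 0.27) and lncRNA:roX2 (−3.17 ± 0.53). By edgeR, 3835 genes passed an adjusted p of 0.05, 1881 higher and 1954 lower.

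Futsch, chic and Rac1, mRNAs long described as Fmr1 targets, did not pass over IgG, at 0.53 ± 0.25 (adjusted p = 0.106), 0.32 ± 0.20 (0.225) and 0.27 ± 0.19 (0.289). Without wild-type IgG library 2, futsch (0.74, adjusted p = 0.0230) and Rac1 (0.45, adjusted p = 0.0494) passed. Of the m6A writers and readers, Flacc alone passed, at 1.27 ± 0.39 (adjusted p = 0.0139). Its call was lost without wild-type Fmr1 library 2 (0.95, adjusted p = 0.0622), IgG library 5 (1.03, 0.0686) or IgG library 7 (1.15, 0.0519). The gene fl(2)d passed without IgG library 7 (0.65, 0.00757). The others had fl(2)d (0.39 ± 0.19), Mettl3 (0.49 ± 0.42), Hakai (0.21 ± 0.38) and nito (0.15 ± 0.19). None of Ythdc1 (0.15 ± 0.27), vir (0.097 ± 0.21), Ythdf (−0.025 ± 0.32) and Mettl14 (−0.34 ± 0.35) passed. With RLE size factors the count became 982 higher and 2563 lower, and with upper-quartile factors 1204 and 2333, since the median of all genes moved by −0.22 and −0.16. Replicates 2 and 3 alone gave 4227 genes, replicates 1, 5 and 7 alone 2044, a fit of only the compared groups 1816 and a stricter filter in that fit 823. In simulated counts with 100 genes planted at each fold, 50% of the 2-fold and 91% of the 4-fold genes were recovered, with 6 false calls.

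Synaptic and neuronal lists had the highest medians over IgG in the wild type. The synaptic vesicle and active zone list had 19 higher, 0 lower and 6 not called of 25 genes, with 20 and 0 adjusted over the list alone. The median was 0.80 (camera adjusted p = 1.6e-11, adjusted p = 0.123 with an estimated correlation). The neuron markers had 12 higher, 0 lower and 4 not called of 16 genes, with 12 and 0 adjusted over the list alone. The median was 0.83 (camera adjusted p = 3.77e-07, adjusted p = 0.164 with an estimated correlation). They include the transporters VGlut (1.28 ± 0.21) and VAChT (1.27 ± 0.21). Chromatin regulators had 18 higher, 0 lower and 10 not called of 28 genes, with 19 and 0 adjusted over the list alone. The median was 0.54 (camera adjusted p = 1.67e-06, adjusted p = 0.164 with an estimated correlation). RNA granule and RNA-binding proteins had 13 higher, 0 lower and 14 not called of 27 genes, with 13 and 0 adjusted over the list alone. The median was 0.37 (camera adjusted p = 5.18e-05, adjusted p = 0.164 with an estimated correlation). Translation factors had 10 higher, 3 lower and 9 not called of 22 genes, with 10 and 3 adjusted over the list alone. The median was 0.38 (camera adjusted p = 0.00201, adjusted p = 0.164 with an estimated correlation). Among these were eEF1alpha2 (1.16 ± 0.18) and eIF3b (1.15 ± 0.19). The actin and microtubule cytoskeleton had 10 higher, 3 lower and 20 not called of 33 genes, with 10 and 4 adjusted over the list alone. The median was 0.32 (camera adjusted p = 0.00108, adjusted p = 0.164 with an estimated correlation). The motor Khc (1.07 ± 0.18) and the membrane linker Moe (1.16 ± 0.23) rose. Axon guidance and growth had 8 higher, 1 lower and 27 not called of 36 genes, with 8 and 1 adjusted over the list alone. The median was 0.26 (camera adjusted p = 0.0166, adjusted p = 0.531 with an estimated correlation). Its risen members include Sema1b (0.71 ± 0.12) and Pak (0.84 ± 0.18). The photoreceptor markers had 10 higher, 1 lower and 14 not called of 25 genes, with 11 and 1 adjusted over the list alone. The median was 0.31 (camera adjusted p = 2.93e-05, adjusted p = 0.164 with an estimated correlation). The channel trp (0.97 ± 0.17) was 1 of them. Ubiquitin ligases and proteasome had 14 higher, 2 lower and 28 not called of 44 genes, with 16 and 4 adjusted over the list alone. The median was 0.23 (camera adjusted p = 0.000945, adjusted p = 0.303 with an estimated correlation). The ligases Su(dx) (0.84 ± 0.13) and Nedd4 (0.92 ± 0.16) rose and the proteasome subunit Prosbeta4 (−1.23 ± 0.24) fell. Neurotransmitter receptors had 7 higher, 0 lower and 25 not called of 32 genes, with 7 and 0 adjusted over the list alone. The median was 0.25 (camera adjusted p = 0.0288, adjusted p = 0.572 with an estimated correlation). The glia markers had 5 higher, 0 lower and 13 not called of 18 genes, with 5 and 0 adjusted over the list alone. The median was 0.26 (camera adjusted p = 0.0155, adjusted p = 0.306 with an estimated correlation).

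Camera called 6 lists lower over IgG in the wild type, 0 of them with an estimated correlation. Small structured noncoding RNAs had 0 higher, 225 lower and 24 not called of 249 genes, with 0 and 232 adjusted over the list alone. The median was −3.78 (camera adjusted p = 7.39e-47, adjusted p = 0.123 with an estimated correlation). With undetected members at their bound the median was −3.81. Ribosomal proteins had 3 higher, 66 lower and 13 not called of 82 genes, with 3 and 69 adjusted over the list alone. The median was −1.25 (camera adjusted p = 1.45e-11, adjusted p = 0.356 with an estimated correlation). The mitochondrial genome had 0 higher, 12 lower and 15 not called of 27 genes, with 0 and 12 adjusted over the list alone. The median was −2.43 (camera adjusted p = 4.53e-06, adjusted p = 0.304 with an estimated correlation). Its transcripts include mt:ND5 (−3.21 ± 0.60). Nuclear-encoded oxidative phosphorylation had 0 higher, 35 lower and 30 not called of 65 genes, with 1 and 37 adjusted over the list alone. The median was −0.72 (camera adjusted p = 0.00211, adjusted p = 0.474 with an estimated correlation). Ribosomal RNA had 0 higher, 10 lower and 7 not called of 17 genes, with 0 and 12 adjusted over the list alone. The median was −2.04 (camera adjusted p = 0.000519, adjusted p = 0.315 with an estimated correlation). Fat body markers had 1 higher, 8 lower and 9 not called of 18 genes, with 1 and 9 adjusted over the list alone. The median was −0.97 (camera adjusted p = 0.00201, adjusted p = 0.303 with an estimated correlation). The other 12 lists were not called. Published Fmr1 target mRNAs had 5 higher, 2 lower and 9 not called of 16 genes, with 5 and 2 adjusted over the list alone. The median was 0.37 (camera adjusted p = 0.0899). The genes tral and Fmr1 were among those that rose and shot among those that fell. Medians turned negative with RLE size factors for 4 of the lists without a call: m6A pathway (median 0.15, camera adjusted p = 0.353), voltage-gated and potassium channels (median 0.14, camera adjusted p = 0.104), very large proteins (median 0.18, camera adjusted p = 0.147) and muscle markers (median 0.12, camera adjusted p = 0.146). Eye pigment (median 0.42, camera adjusted p = 0.101) and hemocyte markers (median 0.37, camera adjusted p = 0.0667) had positive medians. Those of heat shock and stress (median −1.02, camera adjusted p = 0.589), immune response (median −1.39, camera adjusted p = 0.11) and dosage compensation and sex (median −0.24, camera adjusted p = 0.346) were negative. So were those of mitochondrial ribosomal proteins (median −0.37, camera adjusted p = 0.19) and cuticle proteins (median −0.54, camera adjusted p = 0.104).

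**Figure D3:**
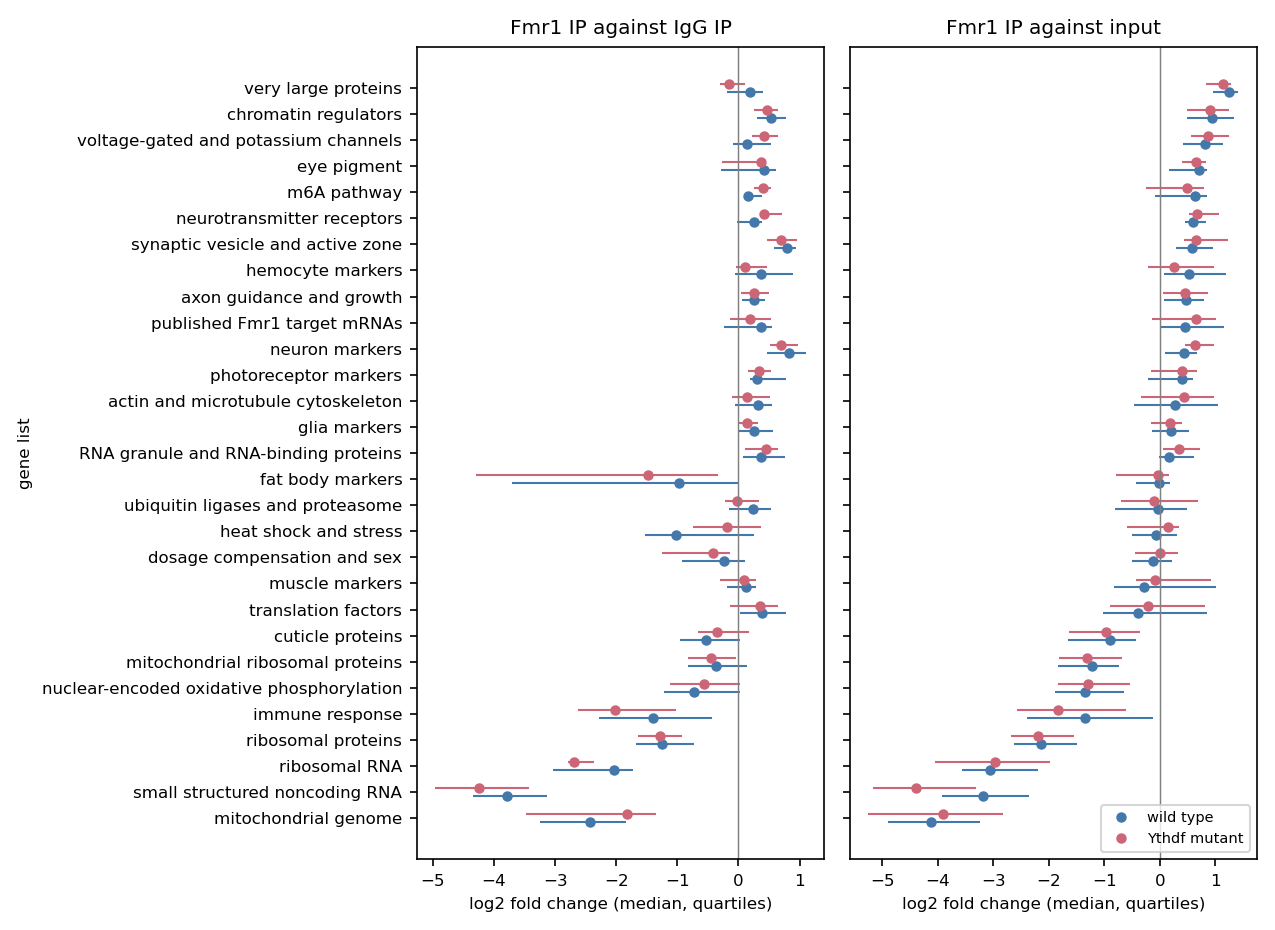
Medians and quartiles of the log2 fold changes of each gene list, over IgG and over input, in both genotypes. Over IgG in the wild type the synaptic vesicle list had a median of 0.80 and the ribosomal proteins −1.25.

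In the Ythdf mutant, synaptic mRNAs again stood above IgG in the Fmr1 libraries (as a list, adjusted p = 0.0715 with an estimated correlation). RpLP0-like had the highest log2 fold change (3.26 ± 0.39, 4 libraries against 4), and below it stood, among others, CG14435 (2.17 ± 0.43), Pkg21D (2.04 ± 0.31) and dan (1.99 ± 0.32). Further risen genes were CG9328 (1.91 ± 0.40), CG7381 (1.74 ± 0.32) and sbr (1.72 ± 0.35). Pkg21D encodes a cGMP-dependent kinase and dan a nuclear factor of eye development. Synaptic mRNAs that rose included VGlut (1.30 ± 0.24), EndoA (1.05 ± 0.17), nSyb (1.02 ± 0.19) and Snap25 (0.98 ± 0.18). RNA and translation factors that rose were Rbp9 (1.00 ± 0.15), Atx2 (0.97 ± 0.18), tral (0.82 ± 0.17) and eIF5B (1.24 ± 0.18). The receptors mAChR-A (1.14 ± 0.22) and mAChR-B (0.99 ± 0.22), the guidance receptor robo3 (0.88 ± 0.19) and Fmr1 (0.67 ± 0.14, adjusted p = 0.00112) rose as well. The fat body proteins Fbp2 (−6.00 ± 0.84), Fbp1 (−5.92 ± 0.81) and Obp99b (−5.46 ± 0.66) fell. So did RNaseP:RNA (−3.48 ± 0.32), RpL37A (−2.63 ± 0.30), Msp300 (−1.78 ± 0.23) and shot (−1.66 ± 0.25) and the immune gene TotA (−3.38 ± 0.62). By edgeR 2341 genes passed, 1239 higher and 1102 lower. Of the 1881 higher and 1954 lower in the wild type, 1031 and 834 passed in the same direction here, where independent lists of these sizes would share 203 and 188. Without mutant Fmr1 library 2 the count was 1394 and without mutant IgG library 7 it was 1473. With RLE size factors it was 650 higher and 1338 lower, with upper-quartile factors 749 and 1263 (median of all genes moved by −0.15 and −0.12). Replicates 2 and 3 alone gave 3089 genes, replicates 1 and 7 alone 324, a fit of only the compared groups 864, a stricter filter in that fit 470 and voom 4428.

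Of the lists called upward in the mutant over IgG, neuron markers and synaptic vesicle genes had the highest medians. Synaptic vesicle genes had 19 higher, 0 lower and 6 not called of 25 genes, with 20 and 0 adjusted over the list alone. The median was 0.69 (camera adjusted p = 2.35e-11, adjusted p = 0.0715 with an estimated correlation). Neuron marker genes had 11 higher, 0 lower and 5 not called of 16 genes, with 12 and 0 adjusted over the list alone. The median was 0.70 (camera adjusted p = 2.79e-08, adjusted p = 0.16 with an estimated correlation). Receptors of neurotransmitters had 5 higher, 0 lower and 27 not called of 32 genes, with 5 and 0 adjusted over the list alone. The median was 0.42 (camera adjusted p = 2.76e-05, adjusted p = 0.334 with an estimated correlation). Regulators of chromatin had 11 higher, 0 lower and 17 not called of 28 genes, with 12 and 0 adjusted over the list alone. The median was 0.46 (camera adjusted p = 6.89e-06, adjusted p = 0.16 with an estimated correlation). RNA granule proteins had 7 higher, 0 lower and 20 not called of 27 genes, with 7 and 0 adjusted over the list alone. The median was 0.45 (camera adjusted p = 2.36e-05, adjusted p = 0.16 with an estimated correlation). Small structured noncoding RNAs, ribosomal proteins, fat body markers and the immune response had camera calls downward. The small RNAs had 0 higher, 215 lower and 34 not called of 249 genes, with 0 and 230 adjusted over the list alone. The median was −4.24 (camera adjusted p = 6.76e-64, adjusted p = 0.0715 with an estimated correlation). With undetected members at their bound the median was −4.27. The ribosomal proteins had 2 higher, 64 lower and 16 not called of 82 genes, with 2 and 69 adjusted over the list alone. The median was −1.28 (camera adjusted p = 1.58e-24, adjusted p = 0.203 with an estimated correlation). The fat body markers had 1 higher, 9 lower and 8 not called of 18 genes, with 1 and 9 adjusted over the list alone. The median was −1.48 (camera adjusted p = 2.38e-08, adjusted p = 0.0715 with an estimated correlation). The immune genes had 0 higher, 7 lower and 15 not called of 22 genes, with 0 and 8 adjusted over the list alone. The median was −2.01 (camera adjusted p = 0.000153, adjusted p = 0.311 with an estimated correlation). Of the m6A list, Flacc (1.23 ± 0.42) and fl(2)d (0.61 ± 0.21) passed. The others had Mettl3 (0.53 ± 0.45), nito (0.52 ± 0.21), Ythdc1 (0.40 ± 0.30) and Hakai (0.28 ± 0.40). None of vir (0.26 ± 0.22), Mettl14 (−0.16 ± 0.40) and Ythdf (−0.39 ± 0.38) passed. Flacc lost its call without mutant Fmr1 library 2 (0.97, adjusted p = 0.160) or 3 (0.88, 0.173) or IgG library 1 (1.17, 0.0981), 2 (1.18, 0.0995) or 7 (0.99, 0.176). For fl(2)d this held without Fmr1 library 1 (0.45, 0.175), 2 (0.55, 0.129) or 3 (0.56, 0.102) or IgG library 1 (0.57, 0.0930), 2 (0.57, 0.0982) or 3 (0.55, 0.110). Futsch had 0.13 ± 0.28, chic 0.056 ± 0.22 and Rac1 0.39 ± 0.20, with adjusted p = 0.812, 0.913 and 0.188.

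All 11469 genes were tested for a difference between genotypes in Fmr1 over IgG, and none passed by edgeR. The smallest p-values belonged to Dnaaf3 (2.91 ± 0.53, adjusted p = 0.0542), a dynein assembly factor, and the peptidase gene Nep5 (2.67 ± 0.50, adjusted p = 0.0542). The phosphodiesterase Pde11 followed (−1.13 ± 0.22, adjusted p = 0.0634). A negative value means a lower ratio of Fmr1 to IgG in the mutant, for RNAs above and below IgG alike. Others with small p-values were Ugt35B1 (−2.01 ± 0.44) and Raf (0.83 ± 0.20). Some of these ratios rest on few counts. Dnaaf3 had 0.387 ± 0.142 CPM in Fmr1 and 1.12 ± 1.16 CPM in IgG libraries of the wild type (17.4 and 10.0 CPM in the mutant). In the mutant Nep5 had 1.65 ± 1.40 CPM in IgG libraries and Ugt35B1 0.565 ± 0.260 CPM in Fmr1 libraries. Among genes tied to RNA, stau (−0.85 ± 0.24) and Rbp9 (−0.40 ± 0.20) had lower and eIF5 (2.02 ± 0.78) higher values without passing. Fmr1 had 0.067 ± 0.19, futsch −0.40 ± 0.37, chic −0.26 ± 0.30, Rac1 0.12 ± 0.28 and Ythdf −0.37 ± 0.50. The m6A genes had fl(2)d (0.22 ± 0.28), nito (0.36 ± 0.29), vir (0.17 ± 0.30) and Ythdc1 (0.25 ± 0.41). None of Flacc (−0.041 ± 0.57), Mettl14 (0.18 ± 0.53), Hakai (0.070 ± 0.55) and Mettl3 (0.042 ± 0.62) passed either. The count was 0 by edgeR with 504 genes at an unadjusted p under 0.05, 0 by limma voom and 5 by DESeq2 (Raf, Dnaaf3, Nep5, Pde11 and lncRNA:CR44603). It was 2 with RLE size factors (Dnaaf3 and Nep5) and 3 with upper-quartile factors (these and Pde11). With the replicate number within library kind as a block, it was 3 (Ugt35C1, asRNA:CR45185 and lncRNA:CR45962) and 1208 at an unadjusted p under 0.05, where the block and these genes were chosen after their values were seen. The 504 genes found with no block are a share under 0.05 of the 11469, fewer than tests with no difference give on average. That shortfall is no evidence that the genotypes are alike. The fit leaves out the correlation of same-numbered libraries, and with the block 1208 genes had such p-values. Without wild-type IgG library 1, Dnaaf3 (2.96, adjusted p = 0.0331) and Nep5 (2.77, 0.0231) passed. This held without library 2 for Dnaaf3 (adjusted p = 0.0362) and without library 7 for Pde11 (−1.22, 0.0449). Planted differences were recovered for 14% of 2-fold and 64% of 4-fold genes, with 1 false call.

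Of the lists, 11 had a camera call for this difference, 10 of them lower in the mutant, and fry called 0 of the 29. Very large proteins had 0 higher, 0 lower and 34 not called of 34 genes, with 0 and 0 adjusted over the list alone. The median was −0.34 (camera adjusted p = 2.88e-06, adjusted p = 0.65 with an estimated correlation). Among them poe (−0.75 ± 0.25), hyd (−0.43 ± 0.18) and brm (−0.50 ± 0.23) did not pass. Fat body genes had 0 higher, 0 lower and 18 not called of 18 genes, with 0 and 1 adjusted over the list alone. The median was −0.51 (camera adjusted p = 5.83e-05, adjusted p = 0.65 with an estimated correlation). The storage protein Lsp1gamma (−1.69 ± 0.50) is 1 of them. This list stood below IgG in both genotypes (medians −0.97 and −1.48). Its median between the IgG libraries of the genotypes was 1.01 (camera adjusted p = 5.85e-05 and adjusted p = 0.492 with an estimated correlation), which by itself lowers the ratio, and its difference over input was −0.081 (camera adjusted p = 0.8). Neurotransmitter receptors were the list with the call upward (median 0.17, camera adjusted p = 0.0059 and adjusted p = 0.706 with an estimated correlation). Their median between the IgG libraries was −0.45 (camera adjusted p = 6.52e-08 and adjusted p = 0.492 with an estimated correlation), which by itself raises the ratio. In wild-type IgG library 7 the receptor list stood a median log2 of 0.87 above the other wild-type IgG libraries (all genes 0.27). The published Fmr1 targets (median 0.041, camera adjusted p = 0.373), axon guidance genes (median 0.075, camera adjusted p = 0.386) and m6A genes (median 0.17, camera adjusted p = 0.386) had no call. The 2531 genes enriched over IgG when both genotypes are pooled had a median difference of −0.077 against 0.043 for the other genes (camera p = 0.00127, p = 0.313 with an estimated correlation), and against no change fry gave p = 0.361. For those at least 2-fold enriched, 308 genes, the median was −0.17. Without mutant Fmr1 library 1 the median of the set was 0.016, and in replicates 2 and 3 alone it was −0.15 and in 1, 5 and 7 alone −0.079. With the 4 doubted IgG libraries set aside, an alternative chosen after seeing the data, it was −0.20. The doubted libraries are those under 500000 counts (wild-type IgG 1 and 2 and mutant IgG 1) and wild-type IgG library 7. Over input the same 2531 genes differed in the opposite direction, with a median of 0.065 against −0.042 for the other genes (camera p = 1.98e-05, p = 0.186 with an estimated correlation), and against no change fry gave p = 0.525. The 2414 genes below IgG had 0.15 over IgG (camera p = 0.0129, p = 0.32 with an estimated correlation) and −0.14 over input (camera p = 0.0002, p = 0.142 with an estimated correlation).

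**Figure D4:**
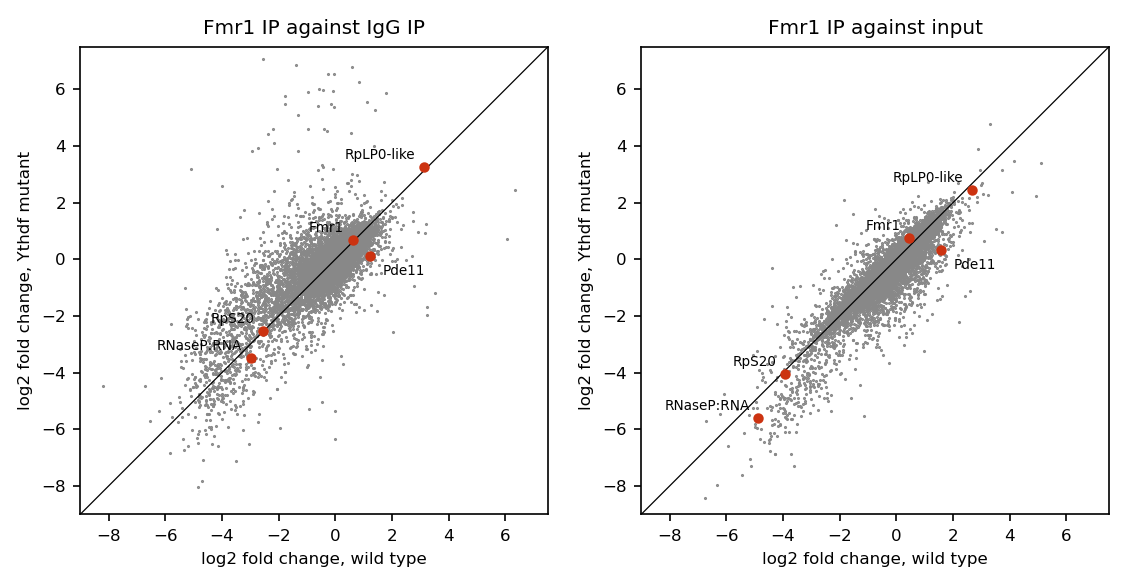
Log2 fold changes in the Ythdf mutant against those in the wild type, over IgG and over input. RpLP0-like had 3.12 and 3.26 over IgG and RpS20 −3.93 and −4.06 over input.

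Against input, single mRNAs of neuronal and chromatin proteins rose in the Fmr1 libraries of the wild type and single mitochondrial and ribosomal transcripts fell. The highest values included the nuclease gene mei-W68 (3.02 ± 0.43), RpLP0-like (2.67 ± 0.25), CG10669 (2.54 ± 0.20) and FoxP (2.42 ± 0.38) and the presynaptic calcium channel cac (2.32 ± 0.30). The active zone scaffold brp (1.74 ± 0.21), the ubiquitin ligase poe (1.71 ± 0.17), and the chromatin regulators dom (1.65 ± 0.15), trx (1.39 ± 0.15) and brm (1.25 ± 0.15) rose. So did the redox enzyme Mical (1.46 ± 0.18), the receptor nAChRalpha1 (1.63 ± 0.28) and the translation factor eIF5B (1.47 ± 0.16). Futsch, the microtubule-binding protein whose mRNA is a described target, rose by 1.30 ± 0.25 (adjusted p = 0.000109). The values of chic (profilin, −0.87 ± 0.19, adjusted p = 0.00055) and Rac1 (−0.80 ± 0.16, adjusted p = 0.000181) fell. Values over input rise with coding length (Spearman correlation 0.706 in the wild type), and futsch has 16485 coding nt. Futsch, chic and Rac1 were not compared with mRNAs of like length, so these directions alone do not tell bound from unbound mRNAs. Fmr1 rose by 0.44 ± 0.12 (adjusted p = 0.0027). Of the m6A genes, Flacc (1.92 ± 0.37), vir (1.03 ± 0.19), nito (0.85 ± 0.18), fl(2)d (0.63 ± 0.18) and Ythdc1 (0.62 ± 0.26) passed. The values of Hakai (0.51 ± 0.29), Mettl14 (−0.094 ± 0.27), Ythdf (−0.10 ± 0.30) and Mettl3 (−0.12 ± 0.30) did not. The call of Ythdc1 was lost without wild-type input 2 (0.63, adjusted p = 0.0680), 3 (0.59, 0.0868), 5 (0.61, 0.0738) or 7 (0.63, 0.0672) or Fmr1 library 2 (0.33, 0.272) or 3 (0.54, 0.108). Hakai passed without Fmr1 library 1 (0.69, 0.0437). Among the lowest were mitochondrial and small RNAs, mt:ND3 (−6.71 ± 0.76), mt:ND4 (−6.22 ± 0.83), RNaseMRP:RNA (−5.19 ± 0.47) and RNaseP:RNA (−4.87 ± 0.30). The mRNAs of RpS20 (−3.93 ± 0.28), RpS27A (−3.31 ± 0.24) and COX5B (−2.77 ± 0.24) fell as well. By edgeR 5597 genes passed, 2657 higher and 2940 lower, with 6473 in replicates 2 and 3 alone and 3705 in replicates 1, 5 and 7 alone.

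Lists of long and neuronal mRNAs had camera calls upward over input in the wild type. Very large proteins had 33 higher, 0 lower and 1 not called of 34 genes, with 33 and 0 adjusted over the list alone. The median was 1.24 (camera adjusted p = 1.33e-15, adjusted p = 0.121 with an estimated correlation). The chromatin regulators had 21 higher, 0 lower and 7 not called of 28 genes, with 21 and 0 adjusted over the list alone. The median was 0.94 (camera adjusted p = 7.98e-10, adjusted p = 0.121 with an estimated correlation). Voltage-gated and potassium channels had 13 higher, 0 lower and 7 not called of 20 genes, with 16 and 0 adjusted over the list alone. The median was 0.81 (camera adjusted p = 2.32e-05, adjusted p = 0.306 with an estimated correlation). The synaptic vesicle genes had 14 higher, 1 lower and 10 not called of 25 genes, with 17 and 1 adjusted over the list alone. The median was 0.58 (camera adjusted p = 9.59e-05, adjusted p = 0.221 with an estimated correlation). Axon guidance genes had 17 higher, 2 lower and 17 not called of 36 genes, with 18 and 2 adjusted over the list alone. The median was 0.46 (camera adjusted p = 0.000263, adjusted p = 0.306 with an estimated correlation). The published Fmr1 targets had 8 higher, 2 lower and 6 not called of 16 genes, with 9 and 2 adjusted over the list alone. The median was 0.46 (camera adjusted p = 0.0172, adjusted p = 0.221 with an estimated correlation). Lists of the ribosome and of mitochondria had calls downward. Ribosomal protein genes had 2 higher, 75 lower and 5 not called of 82 genes, with 2 and 75 adjusted over the list alone. The median was −2.14 (camera adjusted p = 6e-29, adjusted p = 0.184 with an estimated correlation). Mitochondrial ribosomal proteins had 0 higher, 60 lower and 11 not called of 71 genes, with 0 and 61 adjusted over the list alone. The median was −1.23 (camera adjusted p = 4.85e-16, adjusted p = 0.121 with an estimated correlation). Oxidative phosphorylation genes of the nucleus had 0 higher, 47 lower and 18 not called of 65 genes, with 2 and 49 adjusted over the list alone. The median was −1.34 (camera adjusted p = 4.92e-15, adjusted p = 0.121 with an estimated correlation). Transcripts of the mitochondrial genome had 0 higher, 24 lower and 3 not called of 27 genes, with 0 and 24 adjusted over the list alone. The median was −4.12 (camera adjusted p = 1.06e-08, adjusted p = 0.221 with an estimated correlation). Of the lists, 19 were called by camera and 22 by fry.

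In the Ythdf mutant, genes that rose over input included mei-W68 (2.70 ± 0.47), RpLP0-like (2.44 ± 0.27), Root (2.38 ± 0.36) and brp (2.09 ± 0.24). So did cac (2.01 ± 0.34), Mi-2 (1.88 ± 0.26), Liprin-alpha (1.74 ± 0.22), eIF5B (1.68 ± 0.18) and para (1.69 ± 0.31). Of the m6A genes vir (1.30 ± 0.21), Flacc (2.17 ± 0.41) and nito (0.79 ± 0.20) rose. Futsch rose by 1.45 ± 0.28 (adjusted p = 0.000149) and Fmr1 by 0.75 ± 0.13 (adjusted p = 4.22e-05). Among those that fell were RNaseP:RNA (−5.62 ± 0.35), RpS20 (−4.06 ± 0.31), RpS27A (−3.58 ± 0.27), ND-MLRQ (−3.08 ± 0.30), mRpS21 (−3.75 ± 0.41) and eIF6 (−1.98 ± 0.24). Chic fell by −0.65 ± 0.22 (adjusted p = 0.0154) and Rac1 by −0.55 ± 0.18 (adjusted p = 0.0142). Both calls were lost without mutant input 1 (chic −0.58, adjusted p = 0.0508, Rac1 −0.45, 0.0825) or 7 (−0.51, 0.0835, and −0.48, 0.0612). So was that of chic without Fmr1 library 3 (−0.50, 0.0807) and that of Rac1 without Fmr1 library 7 (−0.46, 0.0554). As in the wild type, futsch, chic and Rac1 were not compared with mRNAs of like length. Ythdc1 (0.65 ± 0.28), fl(2)d (0.45 ± 0.20), Ythdf (−0.51 ± 0.33), Hakai (0.50 ± 0.32), Mettl14 (−0.30 ± 0.29) and Mettl3 (−0.24 ± 0.32) did not pass. Without Fmr1 library 7 Ythdc1 (0.88, adjusted p = 0.0109) and fl(2)d (0.58, 0.0252) passed. This also held for fl(2)d without input 1 (0.55, 0.0456) or 7 (0.56, 0.0416) and for Ythdf without Fmr1 library 1 (−0.88, 0.0404). By edgeR 5333 genes passed, 2494 higher and 2839 lower, 7092 in replicates 2 and 3 alone, 2146 in replicates 1 and 7 alone and 8330 by voom. Of the wild-type calls 2215 higher and 2447 lower were shared, where independent lists would share 578 and 728. Very large proteins (median 1.15, camera adjusted p = 6.55e-13 and adjusted p = 0.133 with an estimated correlation), chromatin regulators (median 0.91, camera adjusted p = 1.5e-09 and adjusted p = 0.133 with an estimated correlation) and synaptic vesicle genes (median 0.65, camera adjusted p = 1.05e-06 and adjusted p = 0.14 with an estimated correlation) had camera calls upward. In turn, ribosomal proteins (median −2.20, camera adjusted p = 5.21e-28 and adjusted p = 0.152 with an estimated correlation) and small structured noncoding RNAs (median −4.39, camera adjusted p = 2.93e-32 and adjusted p = 0.133 with an estimated correlation, median −4.39 with undetected members at their bound) had calls downward.

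In the wild type 1288 genes were higher over both IgG and input and in the mutant 1003, where independent lists would share 436 and 269 respectively. Simulations with no effect gave 0, which sets no level for lists with real effects that share the Fmr1 libraries. With the Fmr1 libraries divided between the 2 comparisons the numbers were 879 and 829 in the wild type (258 and 256 if independent) and 444 and 522 in the mutant (101 and 134).

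Pde11, a phosphodiesterase that degrades cyclic nucleotides, was the 1 gene whose enrichment over input differed between genotypes by edgeR, with −1.28 ± 0.21 (adjusted p = 0.0178), so it was weaker in the mutant. Its level was 436 ± 24.9 CPM in wild-type and 217 ± 41.2 CPM in mutant Fmr1 libraries, with 144 ± 13.5 and 174 ± 11.5 CPM in the inputs and 184 ± 34.6 and 202 ± 34.3 CPM in the IgG libraries. The call was lost without mutant input 7 (−1.17, adjusted p = 0.0837), wild-type input 2 (−1.21, 0.0519) or wild-type input 7 (−1.23, 0.0645). Its value was −1.12 (adjusted p = 0.124) in replicates 2 and 3 alone and −1.47 (0.806) in 1, 5 and 7 alone. With the lysate as a block 3 genes passed, Pde11, CG18302 and CG1722, and without wild-type Fmr1 library 7 CG18302 passed too. Next came CG1722 (−3.23 ± 0.67), CG13022 (−1.76 ± 0.40) and CG18302 (−1.32 ± 0.31), which did not pass as reported. Fmr1 had 0.31 ± 0.17, futsch 0.15 ± 0.37, chic 0.22 ± 0.29, Rac1 0.25 ± 0.24 and Ythdf −0.40 ± 0.45. The m6A genes had vir (0.27 ± 0.27), Flacc (0.24 ± 0.53), Ythdc1 (0.021 ± 0.38) and nito (−0.060 ± 0.26). None of fl(2)d (−0.17 ± 0.27), Mettl14 (−0.21 ± 0.40), Mettl3 (−0.12 ± 0.43) and Hakai (−0.015 ± 0.42) passed. At an unadjusted p under 0.05 there were 197 genes, voom called 26 and DESeq2 2. These 197 are a share under 0.05 of the 11469 tested, fewer than tests with no difference give on average. Such a shortfall is no evidence that the genotypes are alike. The fit had no block, although same-numbered Fmr1 libraries of the genotypes correlated at 0.63 to 0.776. Synaptic and neuronal lists had camera calls upward. The list of synaptic vesicle genes had 0 higher, 0 lower and 25 not called of 25 genes, with 0 and 0 adjusted over the list alone. The median was 0.23 (camera adjusted p = 0.000513, adjusted p = 0.85 with an estimated correlation). The list of neuron markers had 0 higher, 0 lower and 16 not called of 16 genes, with 0 and 0 adjusted over the list alone. The median was 0.29 (camera adjusted p = 0.000513, adjusted p = 0.85 with an estimated correlation). Over IgG the differences of both lists were not called and had medians of −0.11 and −0.041 (the latter positive with RLE size factors). In mutant inputs the medians were −0.38 and −0.46 (adjusted p = 0.488 for both with an estimated correlation), and a lower input by itself raises a ratio over input. Small structured noncoding RNAs (median −1.16, camera adjusted p = 4.26e-28 and adjusted p = 0.85 with an estimated correlation) had a call downward. Their median in the inputs was 0.75 (adjusted p = 0.613 with an estimated correlation), which by itself lowers the ratio, and their difference over IgG was −0.41. Of the lists fry called 0. Planted differences were recovered for 25% of 2-fold and 84% of 4-fold genes, with 2 false calls.

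The inputs of the genotypes differed in single genes with near absence in 1 stock. The eye pigment transporter gene w had 25.5 ± 5.34 CPM in the mutant and 0.0536 ± 0.0803 CPM in the wild type, a w1118 stock, and sordd2 had 29.5 ± 8.78 against 0.0330 ± 0.0453 CPM. Other genes that rose were CG11893 (7.52 ± 0.64, means of 17.6 CPM in the mutant and 0.0681 CPM in the wild type), Cyp6a17 (7.51 ± 0.47) and lcs (7.33 ± 0.52). Smaller rises were those of Dnaaf3 (5.57 ± 0.36), CG13073 (5.53 ± 0.24) and phr (5.06 ± 0.31). Cyp6a17 is a cytochrome P450 and phr a photolyase. The cuticle gene Cpr51A (2.19 ± 0.29), the hemocyte gene NimC4 (1.05 ± 0.22) and the translation factor eIF6 (1.16 ± 0.22) rose. So did the yolk proteins Yp1 (2.63 ± 0.64) and Yp3 (1.67 ± 0.43). Yp1 lost its call without mutant input 7 (1.76, adjusted p = 0.119) and Yp3 without mutant input 7 (1.02, 0.204) or wild-type input 1 (1.55, 0.0538). The glucosidase gene tobi (−5.42 ± 0.40), the glycosyltransferase gene Ugt35B1 (−4.15 ± 0.24), the eye pigment enzyme v (−4.14 ± 0.38), and the neurotrophin NT1 (−3.10 ± 0.24) fell. So did CG14715 (−3.07 ± 0.26), PK2-R2 (−2.15 ± 0.26) and Cpr72Ec (−1.37 ± 0.23), the receptor mAChR-A (−1.30 ± 0.19) and poe (−0.83 ± 0.18). The m6A genes other than Ythdf had Mettl3 (0.78 ± 0.31), vir (0.56 ± 0.20), Hakai (0.42 ± 0.31) and Mettl14 (0.21 ± 0.28). None of nito (0.19 ± 0.19), Ythdc1 (0.13 ± 0.27), Flacc (0.052 ± 0.38) and fl(2)d (−0.097 ± 0.19) passed. The targets futsch (−0.35 ± 0.26), chic (−0.40 ± 0.21) and Rac1 (0.090 ± 0.17) did not pass either. By edgeR 652 genes passed, 382 higher and 270 lower, 414 without mutant input 7, 1124 in replicates 2 and 3 alone and 326 in 1, 5 and 7 alone. The count was 2264 with only the inputs fitted, 2092 with a stricter filter in that fit, 3198 by voom, 1575 with the replicate number within library kind as a block and 428 at 2-fold or more. The 652 thus depend on the fit that shares 1 spread over all 6 groups, and more genes passed with the inputs alone. Replicates 1, 2, 3 and 7 of the inputs, fitted alone, gave 1969 without and 2242 with the replicate number as a block. The block within library kind and the fit of these replicates without a block were chosen after the data were seen.

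In mutant inputs camera called 10 lists lower and 1 higher, and none was called with an estimated correlation. Synaptic vesicle and active zone genes had 0 higher, 0 lower and 25 not called of 25 genes, with 0 and 4 adjusted over the list alone. The median was −0.38 (camera adjusted p = 2.7e-07, adjusted p = 0.488 with an estimated correlation). Ion channel genes had 0 higher, 1 lower and 19 not called of 20 genes, with 0 and 3 adjusted over the list alone. The median was −0.51 (camera adjusted p = 2.7e-07, adjusted p = 0.488 with an estimated correlation). Genes of neurotransmitter receptors had 0 higher, 3 lower and 29 not called of 32 genes, with 0 and 4 adjusted over the list alone. The median was −0.41 (camera adjusted p = 5.01e-07, adjusted p = 0.488 with an estimated correlation). Neuron markers had 0 higher, 0 lower and 16 not called of 16 genes, with 0 and 2 adjusted over the list alone. The median was −0.46 (camera adjusted p = 1.26e-05, adjusted p = 0.488 with an estimated correlation). Published Fmr1 targets had 0 higher, 1 lower and 15 not called of 16 genes, with 0 and 1 adjusted over the list alone. The median was −0.29 (camera adjusted p = 0.00534, adjusted p = 0.488 with an estimated correlation). The 1 that fell is poe. The other lists with a call downward were muscle markers (median −0.36, camera adjusted p = 0.00361 and adjusted p = 0.694 with an estimated correlation), photoreceptor markers (median −0.25, camera adjusted p = 0.00941 and adjusted p = 0.613 with an estimated correlation) and axon guidance (median −0.20, camera adjusted p = 0.0175 and adjusted p = 0.694 with an estimated correlation). So were very large proteins (median −0.23, camera adjusted p = 0.0142 and adjusted p = 0.694 with an estimated correlation) and oxidative phosphorylation (median −0.18, camera adjusted p = 0.00743 and adjusted p = 0.694 with an estimated correlation). Fat body markers (median 0.45, camera adjusted p = 0.367), hemocyte markers (median 0.15, camera adjusted p = 0.428) and the immune response (median 0.67, camera adjusted p = 0.0965) had positive medians without a call. Small structured RNAs had 6 higher, 2 lower and 241 not called of 249 genes, with 3 and 2 adjusted over the list alone. The median was 0.75 (camera adjusted p = 1.73e-11, adjusted p = 0.613 with an estimated correlation). They were the list called upward, and with undetected members at their bound the median was 0.75. Of the 29 lists 11 were called by camera and 2 by fry. Planted changes were recovered for 58% of 2-fold and 96% of 4-fold genes, with 2 false calls.

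The IgG libraries of the genotypes differed for many of the same genes as the inputs. Of the calls 197 were shared in direction and 0 were opposite, with 27.9 shared if the lists were independent. Genes that rose in mutant IgG libraries were w (5.72 ± 0.54), lcs (5.27 ± 0.64), CG11893 (4.49 ± 0.78) and phr (4.29 ± 0.44). So did Obp56a (4.17 ± 0.44) and CG13073 (3.63 ± 0.32) and the histone demethylase gene Su(var)3-3 (3.50 ± 0.26). Cyp6a17 had 38.5 ± 13.9 CPM against 0.161 ± 0.279 CPM. The lipid carrier apolpp (1.23 ± 0.22), Cpr51A (2.18 ± 0.44) and the RNA-binding protein Rbp9 (0.71 ± 0.15) rose too. Those that fell included tobi (−3.18 ± 0.47), CG17005 (−2.87 ± 0.52), NT1 (−2.54 ± 0.40) and GstE4 (−2.46 ± 0.42), the octopamine receptor Oamb (−1.19 ± 0.22) and Cpr72Ec (−1.16 ± 0.24). Fmr1 had 0.23 ± 0.14, Ythdf −0.93 ± 0.38, futsch 0.20 ± 0.26, chic 0.085 ± 0.21 and Rac1 0.23 ± 0.22. The other m6A genes had vir (0.66 ± 0.23), Mettl3 (0.61 ± 0.54), Flacc (0.34 ± 0.43) and Hakai (0.33 ± 0.46). None of Ythdc1 (−0.096 ± 0.31), Mettl14 (−0.18 ± 0.45), nito (−0.24 ± 0.22) and fl(2)d (−0.49 ± 0.22) passed. Channel genes had 0 higher, 2 lower and 18 not called of 20 genes, with 0 and 11 adjusted over the list alone. The median was −0.57 (camera adjusted p = 6.52e-08, adjusted p = 0.492 with an estimated correlation). Receptor genes had 0 higher, 4 lower and 28 not called of 32 genes, with 0 and 10 adjusted over the list alone. The median was −0.45 (camera adjusted p = 6.52e-08, adjusted p = 0.492 with an estimated correlation). Markers of fat body had 3 higher, 1 lower and 14 not called of 18 genes, with 7 and 1 adjusted over the list alone. The median was 1.01 (camera adjusted p = 5.85e-05, adjusted p = 0.492 with an estimated correlation). Genes of ribosomal proteins had 0 higher, 0 lower and 82 not called of 82 genes, with 0 and 0 adjusted over the list alone. The median was 0.13 (camera adjusted p = 2.45e-06, adjusted p = 0.802 with an estimated correlation). Wild-type IgG library 7 differed from the other wild-type IgG libraries for some of these lists. Its median log2 gaps were 1.19 for channels, 0.87 for receptors, −1.36 for ribosomal proteins and −0.067 for fat body, with 0.27 over all genes. List medians without this library are not given here. By edgeR 490 genes passed, 240 higher and 250 lower, with 189 and 303 by RLE size factors and 1219 with the replicate number within library kind as a block. Without wild-type IgG library 7 the count was 164 and without mutant IgG library 7 it was 208. It was 168 in replicates 2 and 3 alone and 185 in 1, 5 and 7 alone, 47 with only the IgG libraries fitted, 2 with a stricter filter in that fit and 82 by voom. The 490 calls, and the 197 shared with the inputs, thus rest on the fit that shares 1 spread over all 6 groups. The shared calls were not recounted with the IgG libraries fitted alone. Replicates 1, 2, 3 and 7 of the IgG libraries, fitted alone, gave 34 without and 88 with the replicate number as a block. As for the inputs, the fits that gave 1219 and 34 were chosen after the data were seen, as were the sets of replicates. Planted changes were recovered for 44% of 2-fold and 82% of 4-fold genes, with 5 false calls.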

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

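The tests of other splits of the samples, of linkage, of stock background, of pull-down strength and of handling shared by both pull-downs were chosen after the results they bear on were seen. Those of the inputs of replicates 2 and 3, of length in IgG libraries against input and of the count floor were written first.

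Of 72 groups of values tested for a library far from the others, 7 held one, where chance gives 3.6. Mutant input 7 had 9207492 counts in genes against 14391664 to 15459370 in the others, mutant Fmr1 library 2 had 54195136 against 10726339 to 14199826, and wild-type IgG library 7 had 5879253 against 196933 to 1430172. Chic stood at 1121 CPM in wild-type input 1 (others 682 to 771) and at 685 CPM in mutant input 7 (593 to 607), Rac1 at 50.0 CPM in wild-type IgG library 2 (23.8 to 28.2) and Pde11 at 156 CPM in mutant Fmr1 library 1 (232 to 246).

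A difference between genotypes passed for Pde11 over input (−1.28). Camera also called 15 lists, of which 0 passed with an estimated correlation and 0 by fry. It does not test the list medians, which are given here for size and direction. Over IgG these were cytoskeleton −0.11, neurotransmitter receptors 0.17, very large proteins −0.34, translation factors −0.15, ubiquitin −0.13, immune response −0.28, photoreceptor markers −0.15, fat body −0.51, ribosomal proteins −0.021 (positive with RLE size factors), small structured noncoding RNA −0.41 and ribosomal RNA −0.39. Over input they were synaptic vesicle 0.23, neuron markers 0.29, photoreceptor markers 0.13 and small structured noncoding RNA −1.16.

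The first pattern weighed is that Fmr1 signal rises with coding length, with a Spearman correlation in the wild type of 0.706 over input (95% interval 0.694 to 0.717) and 0.415 over IgG (0.399 to 0.431). IgG over input rises with length too (0.482, 0.466 to 0.498), so better recovery of long mRNAs by any pull-down may explain part of the signal over input. Whether the part over IgG comes from a recovery that differs between the pull-downs was not tested. A count floor in shallow IgG libraries as the whole cause is argued against by 0.202 (0.152 to 0.247) among 1616 genes of high level. A part played by the floor stays open, as this value is lower than the 0.415 of all coding genes. The intervals of correlations and median gaps in this and the next pattern come from 200 resamplings of genes. They leave out the spread between libraries. No biological explanation was tested.

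The second is that Fmr1 libraries of replicates 2 and 3 stand apart from 1, 5 and 7 in both genotypes (correlations of deviations 0.61 to 0.77 within 2 and 3, −0.044 to 0.78 within 1, 5 and 7, so that this set is not uniform, and −0.73 to −0.36 between the sets). The inputs differ between these sets for heat shock genes (−1.29, in Fmr1 libraries −1.24), ribosomal RNA (0.77 and 0.69) and small structured noncoding RNA (1.05 and −0.039). Across genes, gaps in inputs and Fmr1 libraries correlate at 0.229 (0.183 to 0.284), between the bounds set, so how far the inputs explain the pattern stays open. A stronger pull-down in 2 and 3 may contribute, since genes enriched in 1, 5 and 7 have a median gap of 0.206 (0.161 to 0.234), and so may handling shared by both pull-downs, since the gap in IgG libraries correlates at 0.673 (0.655 to 0.693). Within each set the counts are given beside the pooled ones above, except for the 2 differences between genotypes.

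The third is that inputs differ between genotypes in single genes. Of 650 called genes with a position 344 (52.9%, 49.0 to 56.8) lie on chromosomes other than that of Ythdf, which argues against linked variants that each change their own gene for these. For calls near Ythdf such variants stay open as a cause, since the share within 2 Mb (27 of 437 genes) is 1.09 times that elsewhere (0.749 to 1.58). Effects of a linked variant on distant genes were not tested. A different stock background cannot be told apart from the mutation, as each genotype is 1 stock, and 59 called genes had at most 3 counts in every input of 1 genotype, 40 of them in the wild type and 19 in the mutant.

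For the inputs, no other split of the samples gave as many genes (652, highest other 214, 1 of 100 splits as large, the real one). This would exclude chance only if same-numbered inputs were independent, and their correlations were −0.0473 to 0.394. The splits that part all pairs (highest other 183 among 14) are too few for a share under 0.05. In the next comparisons the libraries are paired by lysate or go together by number, and the splits that part all pairs are again too few. These are Fmr1 over IgG in the wild type (3835, highest other 2528, 1 of 100 as large; 1176 among 14 that part pairs) and the mutant (2341, 772, 1 of 35; 19 among 8), and Fmr1 over input in the wild type (5597, 1752, 1 of 100; 774 among 14) and the mutant (5333, 771, 1 of 35; 0 among 8). Too few are also left for the IgG genotype comparison (490, 549, 3 of 100; 179 among 15), where the splits with more exchanged wild-type IgG library 1 or 2. The difference over IgG had 0 genes, so no split could give fewer and nothing was tested (highest other 1, 100 of 100). The difference over input had 1 (669, 4 of 100; 0 among 11). Its highest other came from parting lysates 2 and 3 of both genotypes from the rest, which is the structure of the second pattern.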

How the results depend on the processing

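The alternatives that set aside 4 doubted IgG libraries, use only replicates 2 and 3 or only 1, 5 and 7, fit replicates 1, 2, 3 and 7 of inputs or IgG libraries without a block, or block by number within library kind were chosen after seeing the data; the others were planned. Every alternative kept its direction for the Ythdf level, and the counts of Fmr1 over IgG and over input stayed within 1.5 times except as follows and in the ranges at the end. The stricter filter was run with only the compared groups in the fit, so it changes the filter and the fit at once. The cause was not tested unless fewer libraries are named.

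Fmr1 over IgG in the wild type: 2004 at 2-fold or more, 823 with the stricter filter (4460 genes tested), 1816 with only the compared groups and 2044 in replicates 1, 5 and 7. In the mutant: 1216, 470, 864, 324, by voom 4428, and 1394 and 1473 without mutant Fmr1 library 2 or IgG library 7. Their difference: 2 with RLE, 3 with upper quartile, 5 by DESeq2 and 3 with the number-within-kind block.

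Fmr1 over input in the wild type: 2825 at 2-fold or more and 3705 in replicates 1, 5 and 7; in the mutant 2937, 2146 and, by voom, 8330. Their difference: 0 with no filter, 2 with the stricter filter, only the compared groups, DESeq2 or the number block, 26 by voom, 3 with the lysate or number-within-kind block, and 0 in either set of replicates (fewer libraries).

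Inputs: 428 at 2-fold or more, 2092 stricter filter, 2264 only the compared groups, 3198 voom, 1575 number-within-kind block, 1969 and 2242 in replicates 1, 2, 3 and 7 of the inputs alone without and with a number block, 1124 in replicates 2 and 3, 326 in 1, 5 and 7. IgG libraries: 2, 47 and 82 by stricter filter, compared groups and voom, 1219 with the number-within-kind block, 34 and 88 in replicates 1, 2, 3 and 7 of these alone without and with a number block, 150 with doubted libraries set aside, 168 and 185 in the sets of replicates.

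The paired Ythdf difference was −0.93 (permutation p = 0.125, the smallest 4 pairs can give). The median of the enriched set was −0.030 without mutant Fmr1 library 7, −0.019 without mutant IgG library 3, −0.032 without wild-type Fmr1 library 2, and reversed to 0.016 without mutant Fmr1 library 1. Ythdc1 over input in the wild type reversed to −0.0065 in replicates 1, 5 and 7. Of the genes the rule gives and the text leaves out, in replicates 2 and 3 Yp1 in IgG libraries reversed to −0.095 and mRpS21 over IgG in the mutant to 0.14. Over all 1063 values of genes, alternatives ended the call 893 times, added one 497 times and left it 23238 times; the values in the text were picked for holding without single libraries (9 of 159 calls lost, 84 of 418 in the rest).

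With an estimated correlation 0 lists were called in all 8 comparisons, where camera at its preset called 4 to 20. Against no change, fry called 20 and 14 of the 29 lists for Fmr1 over IgG in the wild type and the mutant. Over input fry called 22 and 23, for both differences 0, and for inputs and IgG 2 each. Leaving out 1 library at a time gave 3095 to 3870, 1394 to 2609, 0 to 2, 4925 to 5577, 4428 to 5496, 0 to 2, 414 to 587 and 164 to 613 genes in the order of the comparisons, −1.01 to −0.82 for Ythdf and −0.12 to 0.016 for the enriched set. With 4 doubted IgG libraries set aside, Fmr1 over IgG gave 3391 and 2491 genes.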

Other observations

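All tests in this part, and the genes named in it, were chosen after the data were seen. Coding genes were ranked by length and divided into 5 equal parts. The shortest part (median 471 nt) had, over IgG in the wild type, a median log2 fold change of −0.65 and the longest (3717 nt) 0.35, with −0.13, 0.07 and 0.22 between them. Over input the 5 medians were −1.20, −0.39, −0.01, 0.32 and 0.73. Of 205 snoRNA genes 196 were lower over IgG in the wild type (median −3.91).

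Wild-type IgG library 7 held lncRNA:Hsromega at 19819 CPM (other wild-type IgG libraries 1230 to 3169, highest of all others 3638), Hsp26 at 224 CPM (0 to 54.2, highest 508) and Hsp68 at 323 CPM (11.0 to 57.4, highest 435). So Hsp26 and Hsp68 reach higher levels in libraries of other groups. Of the reads of wild-type IgG library 7, 37.2% lay in no feature (9.61% to 19.3% in the other wild-type IgG libraries). Of the lists, heat shock (2.73) and channels (1.19) had the highest median log2 gaps between this library and the other wild-type IgG libraries. Ribosomal RNA (−1.86) and ribosomal proteins (−1.36) had the lowest. In replicates 2 and 3 against 1, 5 and 7, heat shock genes had median gaps of −1.24 in Fmr1 libraries, −1.29 in inputs and −1.04 in IgG libraries, and ribosomal RNA 0.69, 0.77 and 1.29.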
